A study of Mus musculus with 12 samples.

How the data were processed

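The data were 12 libraries of polyadenylated RNA from C57BL/6 mouse cells, 3 in each of 4 groups: granulocyte-macrophage progenitors (GMP) of wild type (WT) and Xbp1-deficient (KO) mice, and GMP transduced with GATA2, re-sorted and cultured for 48 hours (GATA2-GMP) of both genotypes. Per the labels, GMP were sorted straight into Trizol and made into libraries with a TruSeq kit, and GATA2-GMP RNA was amplified with a SMARTer Ultra Low Input kit before TruSeq, so stage, transduction, culture and kit change together. The labels give neither the Xbp1 allele nor the animals behind each replicate number.

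The values used were the authors' raw counts of reads per gene symbol, 1 table per library, without normalization, judging by whole numbers with a different sum in each library. The authors name build mm9, STAR 2.3.0, SAMtools 0.1.14, HTSeq and DESeq without saying what each was used for, and strand setting, annotation and read filters are not stated. Each table held 23366 genes and 5 counter rows for reads that went to no gene, which were set aside before library sizes were computed. These rows held 55.8 to 66.5% of all records per library; reads with more than 1 alignment came to 40.3 to 54.96% of records, as alignments, so that the shares are not shares of reads.  In the tables of the 6 GMP libraries 27 gene names had been turned into dates by a spreadsheet; 23 were restored to the only gene name of the GATA2-GMP tables that the date can stand for, and 4 whose date has more than 1 such name (Marc1, Marc2, March1 and March2) were left out of all libraries, which left 23362 genes. No library repeated another: the pair most alike had unequal counts in 14460 genes.

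Library totals ran from 8220484 (GMP KO 3) to 33645602 counts (GMP KO 2), so that 1 CPM stood for at least 8.22 reads. The 10 genes with the most counts took 18.2 to 23.7% of the counts in GATA2-GMP WT and 11.8 to 14.0% in GATA2-GMP KO. Genes with a count numbered 14439 to 14580 in GMP WT and 13885 to 15098 in GMP KO.

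Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr on the groups of the comparison, TMM scaling, estimateDisp, glmQLFit with robust=TRUE and glmQLFTest, with p adjusted by Benjamini-Hochberg over all genes tested and a threshold of 0.05; each adjusted p of a gene is edgeR's unless another tool is named. Genotype was tested within each stage on its 6 libraries, its difference between the stages as an interaction over all 12, and stage on the 6 WT libraries. Log2 fold changes are KO minus WT, or GATA2-GMP minus GMP; the standard error (SE) is the fold change divided by the square root of its F statistic. Values in CPM used library sizes scaled by TMM among the libraries and genes of each comparison; Xbp1 per library and the figures use the genotype comparison of each stage. Where a group had no reads, a fold was bounded against a floor of 3 counts over the group, and where it had 1 to 3 counts the ratio was given with its 95% counting interval. Calls of the 2 genotype comparisons were compared by Fisher's exact test over genes tested in both, as if independent, which they are not.

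Whether the replicate numbers pair libraries was checked by correlating, across genes, each library's deviation from its group mean with those of the other group. In GMP the same number gave the highest value for each library (0.318, 0.249 and 0.192), so a paired fit with a replicate block was also run. The same numbers gave -0.16, -0.31 and -0.49 in GATA2-GMP and 0.015, 0.011 and 0.045 between the WT groups of the stages, and no pairing was assumed there.

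A set of 24 gene lists written from general knowledge was tested in each comparison with camera of limma 3.58.1 on log2 CPM (prior count 2) at a fixed correlation between genes of 0.01, with p adjusted over the lists with at least 3 tested members. Camera asks whether a list's genes move one way on balance, more than other genes, so members that move opposite ways offset each other. Camera with an estimated correlation was run beside it. Fry was run too, and its p asks whether a list's genes move one way on balance without reference to other genes. The lists were XBP1 targets, ER chaperones and folding enzymes, translocation and N-glycosylation, ER-associated degradation, COPI and COPII vesicle transport, the PERK-ATF4-CHOP arm, sensors of the unfolded protein response, IRE1-dependent decay substrates, eosinophil granule proteins, eosinophil receptors and enzymes, lineage transcription factors, neutrophil primary and later granules, monocytes, macrophages and dendritic cells, mast cells and basophils, erythroid cells and megakaryocytes, lymphoid cells, stem and early progenitor cells, cell cycle, p53 targets and apoptosis, cholesterol synthesis, interferon response, immediate early genes and sex-linked transcripts. Besides the members shared with XBP1 targets, 1 gene each is shared by 6 other pairs of lists; Ela2, Hbb-bt and Ahsp were not found under these names. Median, mean and test of a list differed in sign for lymphoid cells in GMP, for lineage transcription factors, erythroid cells and p53 targets in GATA2-GMP, for decay substrates, mast cells, lymphoid cells and p53 targets in the difference, and for primary granules and monocytes between stages; camera's adjusted p for these 10 ran from 0.356 to 0.963, and from 0.454 to 0.973 with an estimated correlation. A list of 40 hypoxia response genes was added after the calls were seen, without those called in GATA2-GMP (1 fell in GMP).

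Genes were named by a fixed rule: Xbp1 first; the 8 largest rises and 8 largest falls of each genotype comparison, and the 6 largest each way of the other comparisons, among genes past the threshold with a mean of at least 5 CPM in the higher group and, outside the difference, no overlap between groups; up to 4 members of each list described, those with the smallest p; and Dnajb9, Hspa5, Edem1, Sec61b, Ern1, Ddit3, Atf4, Gata1, Gata2, Cebpe, Cebpa, Il5ra, Ccr3, Epx, Prg2 and Mpo. Not all genes that the rule names are reported here. Identifiers without an annotated gene were passed over, and Ear, Hba, Hbb and Stfa genes, of near-identical families, carry the word uncertain. Positions and transcript lengths come from the GENCODE vM1 annotation of mm9, and similarity of transcripts from BLAST 2.17.0.

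Each comparison was also run with DESeq2's size factors in edgeR, with the Wald test of DESeq2 1.42.0, with no filter on low counts, with a mean of at least 5 CPM, with a replicate block, without each library in turn and, for genotype, with all 12 libraries in 1 fit. Chosen after seeing the data were fits with offsets corrected in each library for transcript length or GC content by a loess curve (span 0.5) of the library's log ratio to the mean library, run for GATA2-GMP and the difference (length alone) and with the replicate block for GMP; length was known for 94.5 to 95.3% of tested genes. In a fit that leaves out 1 library of 3, the group has 2 libraries and the spread is pooled over the groups. Each test was also run on all splits of its 6 libraries, or on 100 regroupings within stages for the difference.

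Tests were run on data simulated from the means, library sizes and dispersions of each comparison. Of genes changed 1.5-fold, 2-fold and 4-fold, 73.8, 88.1 and 98.5% were recovered in GMP, 1.49, 13.4 and 76.6% in GATA2-GMP, 0, 4.48 and 59.1% in the difference and 1.54, 18.8 and 76.9% between the stages, with 12, 1, 3 and 5 false calls. Camera called 5 of 5 lists of 30 genes raised 1.5-fold, also with an estimated correlation, and 0 of 20 unchanged lists in each comparison, while fry called 1, 1, 0 and 0 of the unchanged lists. With a simulated length bias, the length correction took recovered genes from 164 to 176 of 200, false calls from 8 to 7 and calls of the biased split from 9 to 0. In the data a split not by genotype called 1453 genes, and 375 once corrected, so structure of that size was not tested.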

Results

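Polyadenylated RNA was sequenced from granulocyte-macrophage progenitors (GMP, the bone marrow cells that give rise to granulocytes and monocytes) of wild-type and Xbp1-deficient C57BL/6 mice, and from GMP that had been transduced with GATA2, a transcription factor of the eosinophil and mast cell lineages, re-sorted and cultured for 48 hours (GATA2-GMP). XBP1 is a transcription factor of the unfolded protein response, made active when the endoplasmic reticulum (ER) sensor IRE1 splices its mRNA. The series asks which transcripts depend on XBP1 at both of these stages of eosinophil development. Each stage had 3 wild-type (WT) and 3 Xbp1-deficient (KO) libraries. Values in CPM (counts relative to library size) were scaled within the libraries of each comparison, so a gene's CPM can differ between comparisons. Mpo, the neutrophil peroxidase, took the largest share of counts in 5 of the 6 GMP libraries, and Prg2, the eosinophil major basic protein, took the largest in all 6 GATA2-GMP libraries. Prg2 held 8.72 to 12.25% of the counts in GATA2-GMP WT and 4.10 to 5.12% in GATA2-GMP KO, and the number of genes with a count was 14558 to 15087 and 15469 to 16455 in these groups. Intervals and lower bounds below cover counting error only, and p-values measure the spread between these samples; whether the 3 libraries of a group came from separate animals is not stated in the labels.

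Xbp1 reads, which at the level of the gene also count exons outside any deleted part, were lower in each KO library than in each WT library of its stage. Xbp1 had 170.1, 173 and 202 CPM in GMP WT 1 to 3 and 115, 70.6 and 76.0 CPM in GMP KO. It had 293, 207 and 151 CPM in GATA2-GMP WT and 76.9, 93.7 and 98.7 CPM in GATA2-GMP KO. The log2 fold change of Xbp1 was -1.06 (SE 0.21, adjusted p = 0.0919) in GMP and -1.28 (SE 0.27, adjusted p = 0.0959) in GATA2-GMP, neither past the threshold of 0.05, and the difference between the stages was -0.24 (SE 0.34, adjusted p = 0.815). Over all alternatives the adjusted p of Xbp1 ran from 5.20e-07 to 0.247 in GMP and from 0.00185 to 0.456 in GATA2-GMP. Xbp1 passed in GMP without KO 1 (adjusted p = 5.20e-07) and in GATA2-GMP without WT 3 (adjusted p = 0.0131). The gene lies on chromosome 11 from 5420662 to 5425896 (plus strand) of build mm9.

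**Figure D1:**
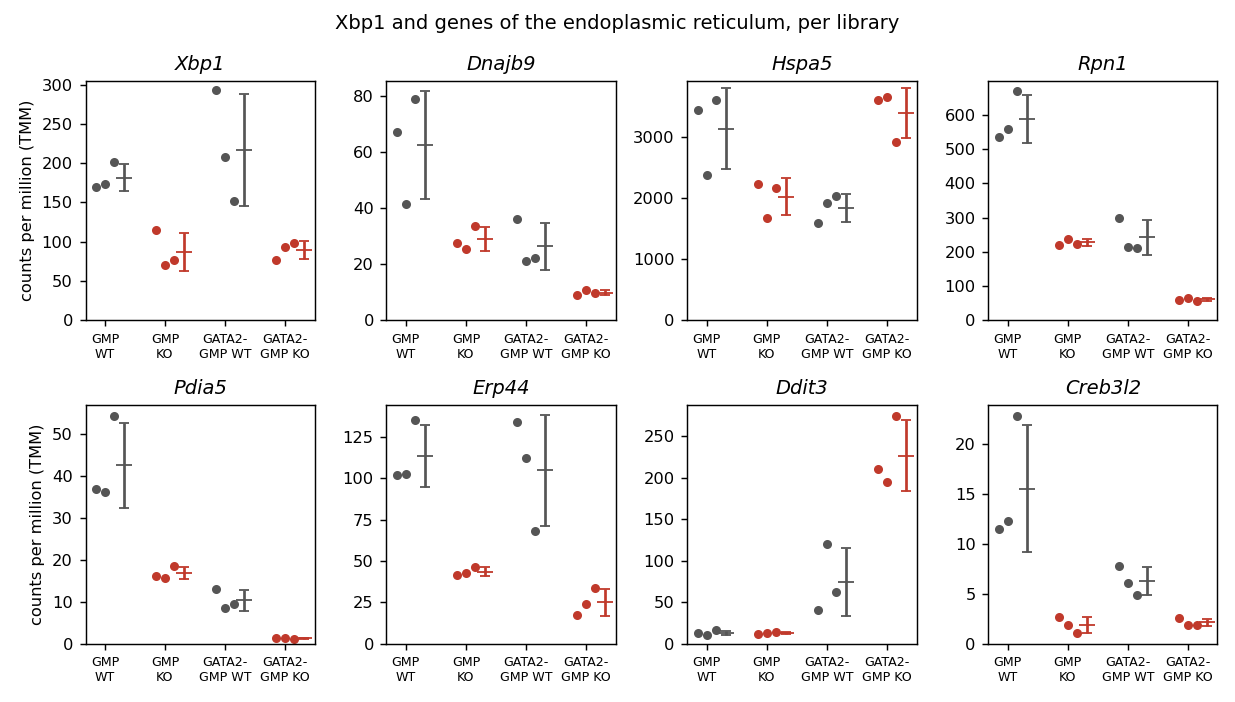
Expression of Xbp1 and 7 genes of the ER and its stress responses in CPM (y axis) in each of the 12 libraries, grouped on the x axis as GMP WT, GMP KO, GATA2-GMP WT and GATA2-GMP KO. Points are libraries, and bars with whiskers are the mean and SD of 3; Rpn1 lies lower in each KO library than in each WT library of its stage, with a mean of 588 ± 71.1 CPM in GMP WT and 227 ± 9.61 CPM in GMP KO.

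The first comparison asked which transcripts depended on XBP1 in freshly sorted GMP. Genes that serve the secretory pathway fell in Xbp1-deficient GMP: Rpn1, a subunit of the oligosaccharyltransferase that glycosylates new proteins, went from 588 ± 71.1 to 227 ± 9.61 CPM (mean ± SD, n = 3 each), a log2 fold change of -1.37 (SE 0.080, adjusted p = 1.31e-05). The ER chaperone Hyou1 fell by 1.21 on the log2 scale (SE 0.077, adjusted p = 1.31e-05), the disulfide isomerase P4hb by 1.14 (SE 0.085, adjusted p = 5.54e-05) and the co-chaperone Dnajc3 by 1.02 (SE 0.076, adjusted p = 2.22e-05). Elane, the neutrophil elastase, fell from 4338 ± 324 to 1914 ± 147 CPM, a log2 fold change of -1.18 (SE 0.069, adjusted p = 1.01e-05), while Mpo had 23674 ± 1859.7 and 22063 ± 1834 CPM, a log2 fold change of -0.10 (SE 0.071, adjusted p = 0.555). Of 12002 genes tested, 79 rose and 302 fell at an adjusted p under 0.05, of which 8 and 37 by over 2-fold. In each of the 381 the KO and WT libraries did not overlap, as in 20.2% of all genes tested, where chance gives 10%. Without GMP KO 3 the count was 209 and without GMP WT 3 it was 237. Since GMP libraries with the same replicate number resembled each other, the test was also run with that number as a replicate block, which called 964 genes, 396 higher and 568 lower, 380 of the 381 among them.

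Among the 8 largest falls were Creb3l2, an ER-anchored transcription factor, at -2.94 (SE 0.38, adjusted p = 0.0101), the potassium channel Kcnk6 at -1.69, the fibrinogen-like protein Fgl2 at -1.69, the calcium-binding Nucb2 at -1.64, Egfl7 at -1.598, Bloc1s1 at -1.58 and the ER prolyl isomerase Fkbp11 at -1.44. Creb3l2 went from 15.5 ± 6.35 to 1.86 ± 0.785 CPM. The 8 largest rises were the receptor Trem2 at 1.23 (SE 0.21, adjusted p = 0.00581), the helix-loop-helix inhibitor Id1 at 1.003 (SE 0.15, adjusted p = 0.00225), Scarf1 at 0.90, Slfn2 at 0.85, Sema4a at 0.85, Rab3il1 at 0.76, the ubiquitin ligase Rnf144b at 0.73 and Bcl3 at 0.72. Adjusted p over these genes ran from 1.31e-05 for Nucb2 to 0.0263 for Sema4a. With 1 library left out the threshold was missed by Bcl3 and Creb3l2 without GMP KO 1 (adjusted p 0.0667 to 0.0668), Creb3l2 and Rab3il1 without GMP KO 2 (adjusted p 0.0647 to 0.0972) and Sema4a without GMP KO 3 (adjusted p = 0.0758). Calls were also lost for Bcl3, Rab3il1 and Sema4a without GMP WT 1 (adjusted p 0.0829 to 0.110), Rab3il1 without GMP WT 2 (adjusted p = 0.0811) and Bcl3, Rab3il1, Scarf1 and Sema4a without GMP WT 3 (adjusted p 0.0516 to 0.125). Kcnk6, Fgl2, Nucb2, Egfl7, Bloc1s1, Fkbp11, Trem2, Id1, Slfn2 and Rnf144b passed in all 6 such fits. With a term for the replicate number Sema4a had 0.83 (adjusted p = 0.0551), with 4.41e-11 to 0.323 over all its alternatives. On mm9, Creb3l2 lies on chromosome 6 from 37277255 to 37392146 (minus strand) and Trem2 on chromosome 17 from 48485726 to 48493472 (plus strand).

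The lists of the secretory pathway, fixed before the data were examined, fell together in GMP, and several share members with the list of XBP1 targets (13 with chaperones, 11 with translocation, 8 with degradation, 3 with vesicle transport). Of 42 XBP1 targets tested, 28 fell (38 fell with p adjusted over the list alone), at a median log2 fold change of -0.71 over the list. The XBP1 targets had camera adjusted p = 4.71e-39, and adjusted p = 0.1001 with an estimated correlation. Of 31 ER chaperones and folding enzymes tested, 20 fell (25 fell with p adjusted over the list alone), with Pdia6 at -0.80 beside Hyou1, P4hb and Dnajc3. The ER chaperones had camera adjusted p = 2.40e-24, and adjusted p = 0.1001 with an estimated correlation. For translocation and N-glycosylation, of 34 genes tested, 23 fell (26 fell with p adjusted over the list alone), among them the signal peptidase subunits Spcs3 (-0.84) and Spcs2 (-0.81) and the oligosaccharyltransferase subunit Magt1 (-0.78). Translocation and N-glycosylation had camera adjusted p = 4.69e-27, and adjusted p = 0.1001 with an estimated correlation. Sec61b, a subunit of the translocon, was at -0.94 (SE 0.079, adjusted p = 3.50e-05). For ER-associated degradation, of 27 genes tested, 5 fell (14 fell with p adjusted over the list alone), among them Vimp (-0.99), Edem1 (-0.57), March6 (-0.46) and Derl1 (-0.32). ER-associated degradation had camera adjusted p = 1.90e-08, and adjusted p = 0.1001 with an estimated correlation. For vesicles between ER and Golgi, of 31 genes tested, 17 fell (23 fell with p adjusted over the list alone), among them the cargo receptors Surf4 (-0.73), Tmed9 (-0.64) and Lman1 (-0.59) and the coat protein Cope (-0.60). COPI and COPII transport had camera adjusted p = 3.18e-22, and adjusted p = 0.1001 with an estimated correlation. Of 10 mRNAs known as substrates of IRE1 tested, 7 fell (8 fell with p adjusted over the list alone), among them Bloc1s1, Erp44 (-1.39), Ergic3 (-0.70) and Hgsnat (-0.81). The decay substrates had camera adjusted p = 1.02e-08, and adjusted p = 0.1001 with an estimated correlation. The ER chaperones Dnajb9, at -1.14 (SE 0.28, adjusted p = 0.159), and Hspa5 (BiP), at -0.63 (SE 0.21, adjusted p = 0.283), did not pass. With the replicate block Dnajb9 had -1.06 (adjusted p = 0.00123) and Hspa5 -0.62 (adjusted p = 5.39e-07), with 7.00e-05 to 0.432 and 3.97e-07 to 0.829 over all alternatives. With 1 library left out, camera's adjusted p for these 6 lists stayed at or under 2.41e-06, and the count for ER-associated degradation was 3 without GMP KO 3; the replicate block gave it 11. Among the genes named here the threshold was missed by Derl1 without GMP KO 3 (adjusted p = 0.0546) and passed by Dnajb9 and Hspa5 without GMP WT 2 (adjusted p 7.00e-05 to 0.00865).

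Of 11 sensors of the unfolded protein response and relatives tested, 4 fell, including Atf6b and Creb3l2 (5 with p adjusted over the list alone). Xbp1, lower by design, is a member. The sensors had camera adjusted p = 0.00258, and adjusted p = 0.1001 with an estimated correlation. Atf6b had -0.45 (SE 0.063, adjusted p = 0.00111) and Ern1, which encodes IRE1, 0.13 (SE 0.072, adjusted p = 0.453). Genes induced by ATF4 and CHOP, the PERK arm of the response, went the other way. Of 32 tested, 3 rose (7 with p adjusted over the list alone). The PERK arm had camera adjusted p = 2.08e-05, and adjusted p = 0.309 with an estimated correlation. The 3 were the pseudokinase Trib3 at 2.69 (SE 0.56, adjusted p = 0.0226) and the mitochondrial one-carbon enzymes Shmt2 at 0.26 and Mthfd2 at 0.33. Atf4 itself had -0.11 (SE 0.070, adjusted p = 0.528) and Ddit3, which encodes CHOP, -0.052 (SE 0.15, adjusted p = 0.908). For cholesterol synthesis, of 23 genes tested, 3 fell (5 fell with p adjusted over the list alone), including Insig1 and Srebf2. Cholesterol synthesis had camera adjusted p = 0.00867, and adjusted p = 0.541 with an estimated correlation. Insig1, which retains the sterol regulator SREBP in the ER, had -0.91 (SE 0.15, adjusted p = 0.0101) and Srebf2, which encodes such a regulator, -0.38 (SE 0.075, adjusted p = 0.0145). For this list camera's adjusted p was 0.152 without GMP WT 1 and 0.116 without GMP KO 2, within 0.000724 to 0.152 over all fits at the fixed correlation. Of the sensors 2 were called without GMP WT 3 or GMP KO 2, and of cholesterol synthesis 1 without GMP WT 3, GMP KO 1 or GMP KO 3. Of the PERK arm 1 was called without each of GMP WT 1, 2 and 3, and edgeR called none without GMP KO 3; with all libraries 12 were higher at unadjusted p under 0.05 and DESeq2 called 5. With the replicate block 9 members of the PERK arm and 5 of cholesterol synthesis were called. The threshold was missed by Creb3l2 and Insig1 without GMP KO 1 (adjusted p 0.0531 to 0.0668), Creb3l2 and Mthfd2 without GMP KO 2 (adjusted p 0.0681 to 0.0972) and Mthfd2, Shmt2, Srebf2 and Trib3 without GMP KO 3 (adjusted p 0.0554 to 0.108). It was also missed by Shmt2 and Trib3 without GMP WT 1 (adjusted p 0.0744 to 0.103), Mthfd2, Shmt2 and Trib3 without GMP WT 2 (adjusted p 0.0578 to 0.0880) and Mthfd2, Srebf2 and Trib3 without GMP WT 3 (adjusted p 0.0606 to 0.103).

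Most single genes of granules and lineages did not pass in GMP. For the later granules of neutrophils, of 17 genes tested, 1 rose (1 rose and 1 fell with p adjusted over the list alone). Later granules had camera adjusted p = 0.000370, and adjusted p = 0.475 with an estimated correlation. The gene that rose, Cd177, had 1.38 (SE 0.21, adjusted p = 0.00219), and Lcn2 had 1.03 (SE 0.29, adjusted p = 0.172). With the replicate block 11 later granule genes rose and 1 fell, and Lcn2 had 0.98 (adjusted p = 0.00498), against 0.000425 to 1 over all alternatives. For the primary granules, of 13 genes tested, 1 fell (4 fell with p adjusted over the list alone), namely Elane. Primary granules had camera adjusted p = 0.176, and adjusted p = 0.572 with an estimated correlation. Prtn3, another protease of these granules, had -0.31 (SE 0.085, adjusted p = 0.108), or -0.31 (adjusted p = 0.00110) with the replicate block (3.97e-05 to 1 over all alternatives). Of 5 eosinophil granule proteins tested, edgeR called none (none with p adjusted over the list alone). Of the members 1 were higher and 0 lower at unadjusted p under 0.05, and DESeq2 called 0 and 0. Eosinophil granule proteins had camera adjusted p = 0.0315, and adjusted p = 0.541 with an estimated correlation. Their median was 1.21; Prg2 had 138 ± 98.7 CPM in WT and 399 ± 166 CPM in KO, a log2 fold change of 1.54 (SE 0.75, adjusted p = 0.461), the peroxidase Epx 1.54 (SE 0.56, adjusted p = 0.337) and Prg3 1.21 (SE 0.60, adjusted p = 0.466). Of 13 eosinophil receptors and enzymes tested, edgeR called none (5 rose with p adjusted over the list alone). Of the members 7 were higher and 0 lower at unadjusted p under 0.05, and DESeq2 called 1 and 0. Eosinophil receptors and enzymes had camera adjusted p = 0.0177, and adjusted p = 0.309 with an estimated correlation. Il5ra, the interleukin 5 receptor, had 1.23 (SE 0.36, adjusted p = 0.115). With the replicate block Il5ra had 1.22 (adjusted p = 0.00225) and Prg3 1.22 (adjusted p = 0.00379), against 0.00143 to 0.975 and 0.00178 to 1 over all alternatives. Of 22 lineage transcription factors tested, 1 rose (3 rose with p adjusted over the list alone), namely Id1. Lineage transcription factors had camera adjusted p = 0.00340, and adjusted p = 0.309 with an estimated correlation. Gata1 had a log2 fold change of 0.20, Gata2 of -0.085, Cebpe of 0.11 and Cebpa of 0.14 (adjusted p 0.227 to 0.916). With 1 library left out, camera's adjusted p was 0.201 without GMP WT 3 and 0.134 without GMP KO 1 for eosinophil granules (0.00186 to 0.201 over all fits at the fixed correlation), 0.0923 without GMP KO 1 for receptors (0.00260 to 0.0923), 0.0777 without GMP WT 2 for transcription factors (0.000223 to 0.0777) and 0.0151 without GMP KO 1 for primary granules (0.0151 to 0.464). The number of members called became 4 for primary granules without GMP KO 1, 2 for later granules without GMP KO 1 or GMP KO 3, 2 for transcription factors without GMP WT 2 or GMP KO 2, and 1 for receptors without GMP WT 1, GMP KO 1 or GMP KO 2. The replicate block gave 4 for primary granules, 4 for transcription factors and 1 each for eosinophil granules and receptors. The threshold was passed by Lcn2 and Prtn3 without GMP KO 1 (adjusted p 0.00587 to 0.0286), Il5ra without GMP KO 2 (adjusted p = 0.0382), Lcn2 without GMP KO 3 (adjusted p = 0.0146) and Il5ra without GMP WT 1 (adjusted p = 0.0337).

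Lists of other cells and of the cell cycle were tested in GMP too. Of 18 genes of monocytes, macrophages and dendritic cells tested, edgeR called none (1 rose with p adjusted over the list alone). Of the members 4 were higher and 0 lower at unadjusted p under 0.05, and DESeq2 called 1 and 0. Monocyte, macrophage and dendritic cell genes had camera adjusted p = 0.0321, and adjusted p = 0.541 with an estimated correlation. Their median was 0.18, and that of erythroid and megakaryocyte genes -0.34. Of 13 erythroid and megakaryocyte genes tested, edgeR called none (none with p adjusted over the list alone). Of the members 1 were higher and 2 lower at unadjusted p under 0.05, and DESeq2 called 0 and 0. Erythroid and megakaryocyte genes had camera adjusted p = 0.0144, and adjusted p = 0.541 with an estimated correlation. For the cell cycle, of 31 genes tested, 1 rose (1 rose with p adjusted over the list alone), namely the mitotic kinase Plk1 at 0.37 (SE 0.067, adjusted p = 0.00868). Cell cycle genes had camera adjusted p = 0.0418, and adjusted p = 0.541 with an estimated correlation. Monocyte genes called were 1 without GMP WT 1 and 2 without GMP KO 1, and erythroid genes 1 without GMP WT 2 or GMP WT 3; the replicate block gave 5 and 2, and 5 of the cell cycle. Camera's adjusted p was 0.127 without GMP WT 1, 0.331 without GMP KO 2 and 0.162 without GMP KO 3 for monocyte genes (5.56e-05 to 0.331 over all fits at the fixed correlation), 0.148 without GMP WT 3 for erythroid genes (0.000564 to 0.148) and 0.419 without GMP WT 3 and 0.303 without GMP KO 2 for the cell cycle (0.00742 to 0.419). The lists of mast cells and basophils, lymphoid cells, stem and early progenitor cells, p53 targets, interferon response, immediate early genes and sex-linked transcripts did not pass, with camera's adjusted p from 0.199 to 0.967 and from 0.572 to 0.992 with an estimated correlation. The list of stem cell genes passed without GMP WT 2 (adjusted p = 0.0368) and without GMP KO 1 (adjusted p = 0.0235), the interferon list without GMP WT 1 (0.00180) and without GMP KO 3 (0.0450) and the immediate early list without GMP WT 2 (6.26e-05). 

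**Figure D2:**
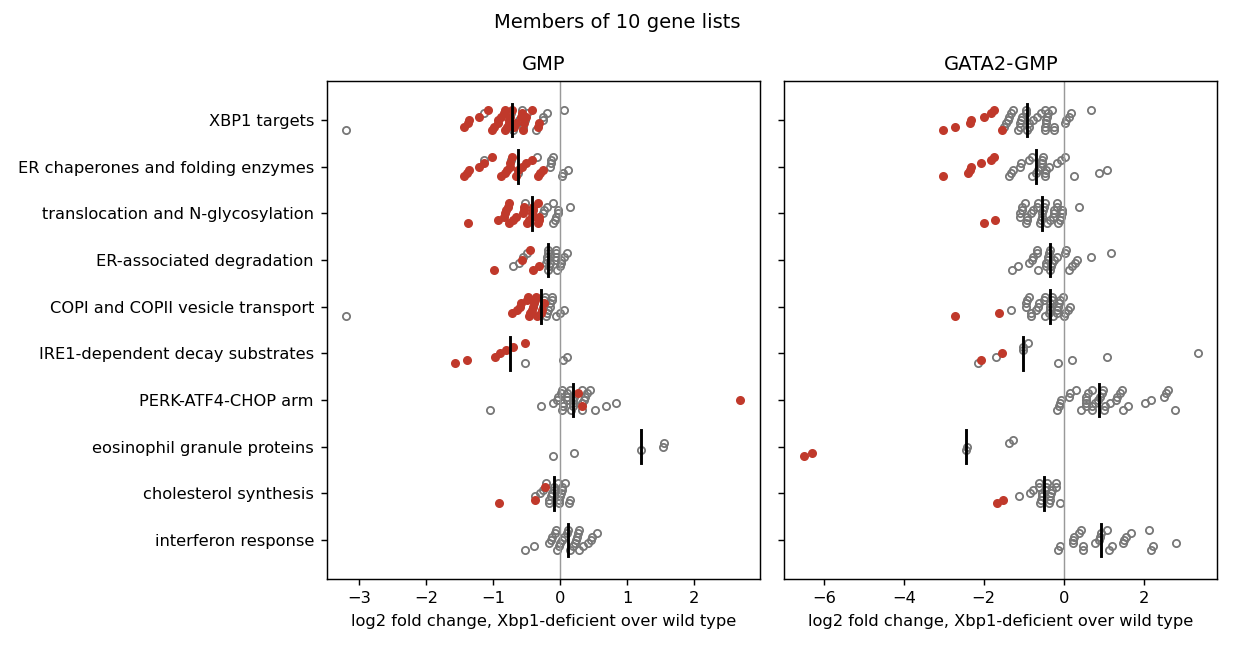
Log2 fold changes (Xbp1-deficient minus wild type, x axis) of the tested members of 10 gene lists in GMP and in GATA2-GMP, with 1 panel per stage and different x scales. Filled points passed the threshold over all genes, open points did not, and black bars mark list medians; the median of the XBP1 targets was -0.71 in GMP and -0.93 in GATA2-GMP.

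The same question was asked of GATA2-GMP after culture. The disulfide isomerases Pdia5 and Txndc5, the COPII coat protein Sec24d and the lysosomal membrane protein Lamp1 fell: Pdia5 went from 10.3 ± 2.50 to 1.26 ± 0.144 CPM (mean ± SD, n = 3 each), a log2 fold change of -3.02 (SE 0.33, adjusted p = 0.00945), and Lamp1 from 262 ± 69.3 to 44.1 ± 4.38 CPM, -2.57 (SE 0.26, adjusted p = 0.00899). Rpn1 fell from 242 ± 50.3 to 60.3 ± 4.11 CPM, -2.004 (SE 0.23, adjusted p = 0.0115). The glucose transporter Slc2a1, at 1.71 (SE 0.23, adjusted p = 0.0264), and the pyruvate dehydrogenase kinase Pdk1, at 2.04 (SE 0.29, adjusted p = 0.0290), rose. Of 11699 genes tested, 12 rose and 32 fell, and in each the KO and WT libraries did not overlap, as in 22.6% of all genes where chance gives 10%. The spread between libraries was larger than in GMP (biological coefficient of variation 30.5% against 7.98%), and the smallest called change was 1.45 on the log2 scale. The count was 8 without GATA2-GMP WT 1, 28 without WT 2, 525 without WT 3 (285 rose and 240 fell) and 20 without KO 2 (10 and 10), and edgeR called none without KO 1 or KO 3 (1000 and 1444 genes at unadjusted p under 0.05), while DESeq2 called 504 with all libraries (239 and 265). It was 3 with the replicate block (Sncaip, Ear1 and Ear2), 294 with no filter (124 and 170), 167 with length-corrected offsets (49 and 118) and 1461 with all 12 libraries in 1 fit (596 and 865). Another split, WT 1, WT 2 and KO 3 against the others, called 1453. Without WT 3, genotype differs from that split in KO 3 alone, so calls gained without WT 3, here and in the difference between stages, may reflect that split. 

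The 8 largest falls were the eosinophil-associated ribonucleases Ear1 at -6.51 (SE 0.67, adjusted p = 0.00899) and Ear2 at -6.30 (SE 0.64, adjusted p = 0.00899), both uncertain since these genes are near-identical to others of their family, the synuclein-binding Sncaip at -4.95, Pdia5, the carbonic anhydrase Car4 at -2.83, Sec24d at -2.73, the kinase Camkk1 at -2.58 and Lamp1. The 8 largest rises were the transglutaminase Tgm2 at 4.13 (SE 0.69, adjusted p = 0.04999), Ankrd37 at 3.25, Adm2 at 3.01, the mitophagy receptor Bnip3 at 2.97, Selenbp1 at 2.82, the acyltransferase Agpat9 at 2.67, Pdk1 and Slc2a1. Their adjusted p ran from 0.00899 for Ear1 to 0.04999 for Tgm2. Of these 16, calls were lost for 11 of 16 without WT 1 (adjusted p 0.0714 to 0.258), 7 of 16 without WT 2 (adjusted p 0.0731 to 0.0908), all 16 without KO 1 (adjusted p 0.0951 to 0.250), Adm2, Camkk1 and Car4 without KO 2 (adjusted p 0.0590 to 0.0634) and all 16 without KO 3 (adjusted p 0.0584 to 0.129). On mm9, Pdia5 lies on chromosome 16 from 35397399 to 35490959 (minus strand) and Pdk1 on chromosome 2 from 71711281 to 71741915 (plus strand).

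The lists of the secretory pathway were lower in Xbp1-deficient GATA2-GMP as well. Of 42 XBP1 targets tested, 8 fell (22 fell with p adjusted over the list alone), at a median of -0.93 over the list, with Dnajb11 at -1.82 and Creld2 at -2.34 beside Pdia5, Rpn1 and Sec24d. The XBP1 targets had camera adjusted p = 1.06e-15, and adjusted p = 0.107 with an estimated correlation. Of 31 ER chaperones and folding enzymes tested, 7 fell (2 rose and 14 fell with p adjusted over the list alone), with Txndc5 at -2.39 and Erp44 at -2.07. The ER chaperones had camera adjusted p = 1.14e-10, and adjusted p = 0.107 with an estimated correlation. For translocation and N-glycosylation, of 34 genes tested, 2 fell (6 fell with p adjusted over the list alone), namely Rpn1 and Ddost (-1.73), both of the oligosaccharyltransferase. Translocation and N-glycosylation had camera adjusted p = 8.92e-08, and adjusted p = 0.202 with an estimated correlation. For vesicles between ER and Golgi, of 32 genes tested, 2 fell (10 fell with p adjusted over the list alone), namely Sec24d and Tmed2 (-1.62). COPI and COPII transport had camera adjusted p = 2.51e-06, and adjusted p = 0.107 with an estimated correlation. Of 11 IRE1-dependent decay substrates tested, 2 fell (1 rose and 6 fell with p adjusted over the list alone), namely Tapbp (-1.54) and Erp44. The decay substrates had camera adjusted p = 0.00113, and adjusted p = 0.107 with an estimated correlation. For ER-associated degradation, of 27 genes tested, edgeR called none (1 rose and 4 fell with p adjusted over the list alone). Of the members 1 were higher and 7 lower at unadjusted p under 0.05, and DESeq2 called 1 and 4. ER-associated degradation had camera adjusted p = 0.00696, and adjusted p = 0.245 with an estimated correlation. For cholesterol synthesis, of 22 genes tested, 2 fell (3 fell with p adjusted over the list alone), among them Insig1 (-1.51). Cholesterol synthesis had camera adjusted p = 1.08e-06, and adjusted p = 0.107 with an estimated correlation. Dnajb9 had -1.43 (SE 0.27, adjusted p = 0.0728), Edem1 -1.13 (SE 0.22, adjusted p = 0.0756), Sec61b -0.93 (SE 0.45, adjusted p = 0.387) and Hspa5 0.88 (SE 0.26, adjusted p = 0.177), with 1839 ± 229 CPM in WT and 3382 ± 412 CPM in KO. Camera's adjusted p for these 7 lists stayed at or under 0.0332 over all fits at the fixed correlation. Without WT 1, 1 XBP1 target and 2 chaperones were called, and no gene of the other lists; without KO 2, 4 XBP1 targets, 3 chaperones, 1 gene each of translocation and of vesicles, and none of the others. Without WT 2, 1 gene each was called for vesicles, decay substrates and cholesterol synthesis, and without KO 1 or KO 3 edgeR called no gene. Without WT 3, 17 XBP1 targets, 8 genes of translocation, 6 of vesicles, 5 decay substrates, 4 of degradation and 4 of cholesterol synthesis were called. Of the genes named here that passed, calls were lost for 9 of 11 without WT 1 (adjusted p 0.0544 to 0.217), Erp44, Insig1, Tapbp and Tmed2 without WT 2 (adjusted p 0.0665 to 0.0908), all 11 without KO 1 (adjusted p 0.122 to 0.281), 6 of 11 without KO 2 (adjusted p 0.0634 to 0.123) and all 11 without KO 3 (adjusted p 0.0584 to 0.129). The threshold was passed by Dnajb9, Edem1 and Sec61b without WT 3 (adjusted p 0.0228 to 0.0383).

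The PERK arm was higher on balance in Xbp1-deficient GATA2-GMP, at a median of 0.88. Of 36 PERK arm genes tested, edgeR called none (16 rose with p adjusted over the list alone). Of the members 21 were higher and 0 lower at unadjusted p under 0.05, and DESeq2 called 13 and 0. The PERK arm had camera adjusted p = 5.18e-12, and adjusted p = 0.107 with an estimated correlation. The members with the smallest p were Shmt2 at 1.32 (SE 0.23, adjusted p = 0.0511), the lipoprotein receptor Vldlr at 2.50 (SE 0.49, adjusted p = 0.0756), Trib3 at 2.56 (SE 0.52, adjusted p = 0.0801) and the asparagine synthetase Asns at 1.48 (SE 0.34, adjusted p = 0.118). Ddit3 had 1.602 (SE 0.37, adjusted p = 0.121), Atf4 0.16 (SE 0.25, adjusted p = 0.823) and Ern1 1.04 (SE 0.43, adjusted p = 0.305). Of 11 sensors tested, Xbp1 included, edgeR called none (4 fell with p adjusted over the list alone). Of the members 1 were higher and 4 lower at unadjusted p under 0.05, and DESeq2 called 0 and 4. The sensors had camera adjusted p = 0.192, and adjusted p = 0.374 with an estimated correlation. Members of the PERK arm were called without WT 1 (1), WT 2 (2) and WT 3 (8), and 4 sensors without WT 3. The threshold was passed by Ddit3 and Trib3 without WT 2 (adjusted p 0.0396 to 0.0496) and Asns, Ern1, Shmt2, Trib3 and Vldlr without WT 3 (adjusted p 0.0189 to 0.0469).

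Granule genes of eosinophils were lower in Xbp1-deficient GATA2-GMP: of 6 genes tested, 2 fell (6 fell with p adjusted over the list alone), namely Ear1 and Ear2 (both uncertain), at a median of -2.43 over the list. Eosinophil granule proteins had camera adjusted p = 1.89e-09, and adjusted p = 0.107 with an estimated correlation. Epx had 15379 ± 9636 CPM in WT and 2868 ± 1022 CPM in KO, a log2 fold change of -2.42 (SE 0.52, adjusted p = 0.0974), and Prg2 109488 ± 24069 and 42345 ± 4143 CPM, -1.37 (SE 0.35, adjusted p = 0.129); neither passed in edgeR, while DESeq2 called all 6 as lower, with adjusted p = 1.02e-05 for Epx and 2.16e-05 for Prg2. Of 18 eosinophil receptors and enzymes tested, 1 rose (1 rose and 4 fell with p adjusted over the list alone), namely Tgm2. Eosinophil receptors and enzymes had camera adjusted p = 0.134, and adjusted p = 0.320 with an estimated correlation. Ccr3, the eotaxin receptor, had -2.39 (SE 0.46, adjusted p = 0.0745), Il5ra -1.02 (SE 0.33, adjusted p = 0.214) and Siglec5 -1.91 (SE 0.35, adjusted p = 0.0648). Of 22 lineage transcription factors tested, edgeR called none (1 rose with p adjusted over the list alone). Of the members 2 were higher and 2 lower at unadjusted p under 0.05, and DESeq2 called 1 and 0. Lineage transcription factors had camera adjusted p = 0.356, and adjusted p = 0.454 with an estimated correlation. Gata1 had -0.43, Gata2 (transduced) -0.12, Cebpe -0.68 and Cebpa -0.047 (adjusted p 0.469 to 0.967). For the primary granules of neutrophils, of 14 genes tested, edgeR called none (2 fell with p adjusted over the list alone). Of the members 1 were higher and 3 lower at unadjusted p under 0.05, and DESeq2 called 1 and 2. Primary granules had camera adjusted p = 0.121, and adjusted p = 0.495 with an estimated correlation. Mpo had -0.46 (SE 0.27, adjusted p = 0.470) and Elane -1.57 (SE 0.43, adjusted p = 0.153). Over all genes the members called became 6 granule genes without WT 3 and none without KO 1 or KO 3, and among receptors 4 without WT 3 and none without WT 1, KO 1 or KO 3; 3 primary granule genes were called without WT 3. Camera's adjusted p was 0.0397 without GATA2-GMP WT 1 for receptors (0.0397 to 0.513 over all fits at the fixed correlation) and 0.00870 without GATA2-GMP WT 3 for primary granules (0.00870 to 0.426). The threshold was passed by Ccr3, Elane, Epx, Prg2 and Siglec5 without WT 3 (adjusted p 0.00397 to 0.0482) and missed by Tgm2 without WT 1 (adjusted p = 0.251), Tgm2 without WT 2 (adjusted p = 0.0790), Ear1, Ear2 and Tgm2 without KO 1 (adjusted p 0.0951 to 0.230) and Ear1, Ear2 and Tgm2 without KO 3 (adjusted p 0.0584 to 0.129).

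Genes of monocytes, macrophages and dendritic cells and of the interferon response were higher on balance in Xbp1-deficient GATA2-GMP, at medians of 0.63 and 0.92, though no single member passed. Of 19 monocyte, macrophage and dendritic cell genes tested, edgeR called none (7 rose with p adjusted over the list alone). Of the members 7 were higher and 1 lower at unadjusted p under 0.05, and DESeq2 called 6 and 0. Monocyte, macrophage and dendritic cell genes had camera adjusted p = 0.000505, and adjusted p = 0.245 with an estimated correlation. Of 24 interferon response genes tested, edgeR called none (none with p adjusted over the list alone). Of the members 6 were higher and 0 lower at unadjusted p under 0.05, and DESeq2 called 4 and 0. The interferon response had camera adjusted p = 2.05e-06, and adjusted p = 0.340 with an estimated correlation. Of class II antigen presentation, H2-Aa had 1.53 (SE 0.29, adjusted p = 0.0689), Cd74 1.66 (SE 0.39, adjusted p = 0.121) and H2-Eb1 1.88 (SE 0.56, adjusted p = 0.176), and of the interferon genes Xaf1 had 2.24 (SE 0.63, adjusted p = 0.155) and Usp18 1.47 (SE 0.45, adjusted p = 0.188). The complement gene C1qb had no reads in the 3 WT libraries and 41 in the 3 KO libraries, at least 13.7-fold higher against a floor of 3 counts over the group. Without WT 3, 3 members of the first list and 1 of the second were called. Fry gave adjusted p = 0.183 for the interferon list. The lists of later neutrophil granules, mast cells and basophils, erythroid cells and megakaryocytes, lymphoid cells, stem cells, cell cycle, p53 targets, immediate early genes and sex-linked transcripts did not pass, with camera's adjusted p from 0.0817 to 0.946 and from 0.320 to 0.943 with an estimated correlation. Later granules passed without GATA2-GMP WT 1 (adjusted p = 0.0197) and without GATA2-GMP KO 2 (adjusted p = 0.0141) and mast cells and basophils without GATA2-GMP WT 2 (0.00272). Single genes past the threshold with a library left out were Cd74, H2-Aa and Usp18 without WT 3 (adjusted p 0.0278 to 0.0436).

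**Figure D3:**
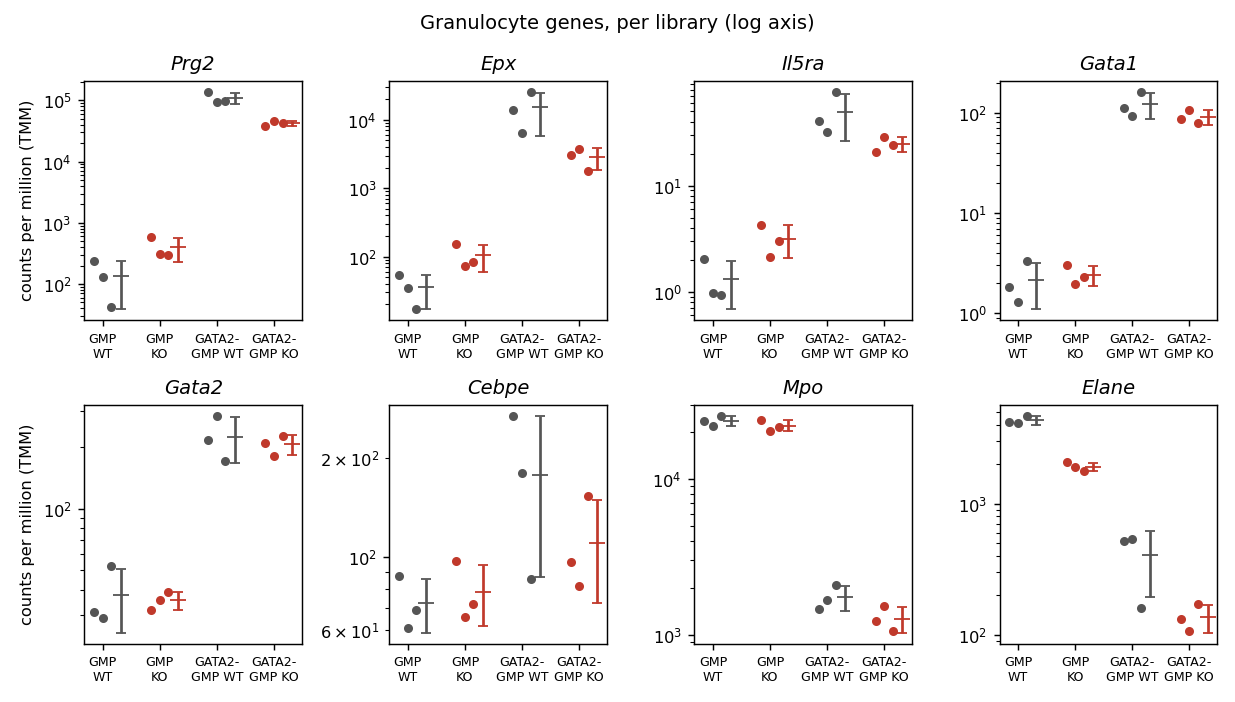
Expression of 8 lineage genes in CPM (log y axis) in each of the 12 libraries, grouped on the x axis by stage and genotype, with the mean and SD of 3 libraries. In GATA2-GMP, Epx had a mean of 15379 ± 9636 CPM in WT and 2868 ± 1022 CPM in KO, and its change did not pass the threshold.

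The calls of both stages were set side by side over the 10941 genes tested in both, to see how far the genotype effect was shared. Of 293 genes that fell in GMP and 30 in GATA2-GMP, 19 were shared, where independence gives 0.803 (odds ratio 66.8, 95% interval 29.9 to 157, Fisher's exact p = 3.15e-23, two-sided). Among these were Rpn1 (-1.37 in GMP and -2.004 in GATA2-GMP), Erp44 (-1.39 in GMP and -2.07 in GATA2-GMP), Pdia5 (-1.36 in GMP and -3.02 in GATA2-GMP), Fkbp11 (-1.44 in GMP and -2.31 in GATA2-GMP) and Lamp1 (-1.35 in GMP and -2.57 in GATA2-GMP), and Creld2, Ddost, Dnajb11, Dnajc3, Emilin1, Entpd7, Insig1, Jkamp, Oaf, Serp1, Tapbp, Tmed2 and Ttc13. Rpn1, Ddost, Erp44, Pdia5, Fkbp11, Creld2, Dnajb11, Dnajc3, Serp1, Tapbp and Tmed2 encode proteins of the ER or its vesicles, and those named here that lie outside the fixed naming rule, like Sva, were named after their values were seen. Of the 293 falls in GMP, 259 (88.4%) had a negative log2 fold change in GATA2-GMP too, against a same sign in 53.6% of all genes; of the 71 rises it was 43 (60.6%). Of 71 rises in GMP and 9 in GATA2-GMP, 1 was shared, Sva (expected 0.0584, Fisher's exact p = 0.0569, two-sided). DESeq2 gave 107 shared calls, 10 rises and 97 falls, where independence gives 1.79 and 6.12.

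**Figure D4:**
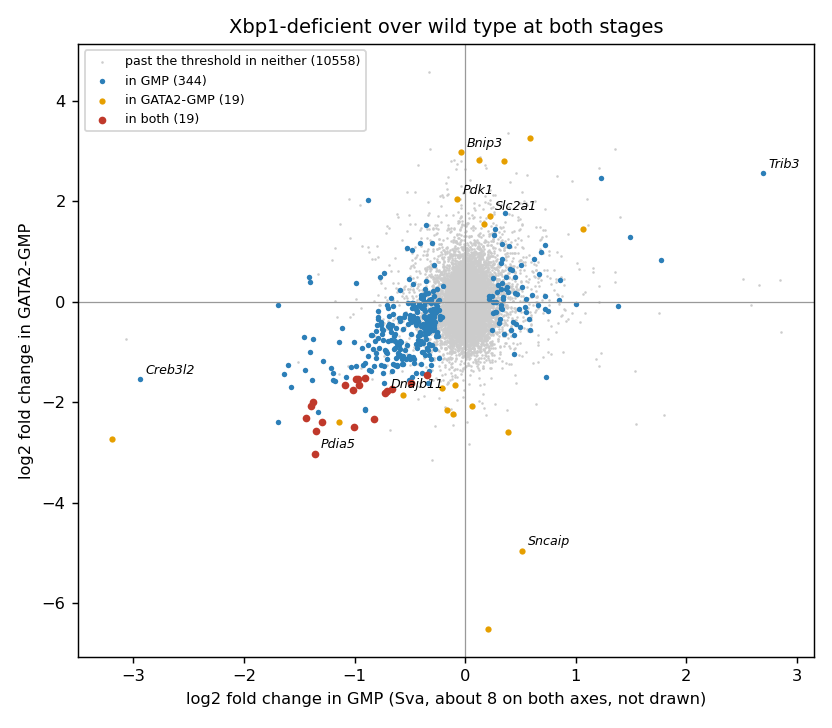
Log2 fold change (Xbp1-deficient minus wild type) in GMP (x axis) against that in GATA2-GMP (y axis) for genes tested at both stages, coloured by the stage in which the gene passed the threshold. Of these genes 344 passed in GMP alone, 19 in GATA2-GMP alone and 19 falls in both; Sva, which had no reads in any WT library, is not drawn.

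The difference between the stages was then tested itself, as the interaction of genotype and stage over all 12 libraries, where a positive value means a higher KO-to-WT ratio in GATA2-GMP than in GMP. Sncaip, at -5.51 (SE 0.60, adjusted p = 0.00733), Camkk1, at -2.98 (SE 0.44, adjusted p = 0.0311), Rnf144b, at -2.24 (SE 0.32, adjusted p = 0.0311), and Tusc1, at -2.13 (SE 0.33, adjusted p = 0.0331), had lower ratios in GATA2-GMP, as did Ear1, at -6.74 (SE 0.92, adjusted p = 0.0278), and Ear2, at -6.58 (SE 1.01, adjusted p = 0.0321) (both uncertain). Pdk1, at 2.09 (SE 0.28, adjusted p = 0.0278), Slc2a1, at 1.47 (SE 0.23, adjusted p = 0.0321), the sulfur dioxygenase Ethe1, at 1.37 (SE 0.21, adjusted p = 0.0321), and Zcchc11, at 1.18 (SE 0.17, adjusted p = 0.0311), had higher ratios. Of 12803 genes tested 11 passed, 4 higher and 7 lower, which includes 1 gene with no annotated name. A replicate block left no call in edgeR (1336 genes at unadjusted p under 0.05), and the 10 named genes had adjusted p 0.138 to 0.291. Of the 10 named, all but Sncaip missed the threshold without any 1 of the 6 GMP libraries, all 10 without GATA2-GMP KO 1 (edgeR called none of all genes, 1687 at unadjusted p under 0.05, and DESeq2 called 716 with all libraries), Slc2a1 without GATA2-GMP WT 1 and Ear2 without GATA2-GMP KO 3. The lost calls had adjusted p 0.0504 to 0.179. The count was 1, 1 and 2 without GMP WT 1, 2 and 3, 1 without each GMP KO library, and 127, 1179, 25 and 28 without GATA2-GMP WT 2, WT 3, KO 2 and KO 3, of which 46, 565, 13 and 17 were higher.

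By camera 6 lists differed in genotype effect between the stages, and 0 with an estimated correlation. For eosinophil granules, of 7 genes tested, 2 were lower (6 were lower with p adjusted over the list alone), at a median of -2.92 over the list. Eosinophil granule proteins had camera adjusted p = 6.17e-08, and adjusted p = 0.155 with an estimated correlation. Epx had -3.99 (SE 0.75, adjusted p = 0.0609) and Prg2 -2.92 (SE 0.70, adjusted p = 0.0960), neither past the threshold in edgeR, while DESeq2 called 5 of the list as lower, these 2 among them. Medians were -0.55 for eosinophil receptors and enzymes, 0.52 for the PERK arm, -0.46 for cholesterol synthesis, 0.28 for monocytes, macrophages and dendritic cells, and 0.78 for the interferon response, or 0.66 with genes that had no reads in a group at their bound. Of 18 eosinophil receptors and enzymes tested, edgeR called none (3 were lower with p adjusted over the list alone). Of the members 1 were higher and 6 lower at unadjusted p under 0.05, and DESeq2 called 1 and 3. Eosinophil receptors and enzymes had camera adjusted p = 0.0194, and adjusted p = 0.155 with an estimated correlation. Of 36 PERK arm genes tested, edgeR called none (4 were higher with p adjusted over the list alone). Of the members 9 were higher and 1 lower at unadjusted p under 0.05, and DESeq2 called 5 and 0. The PERK arm had camera adjusted p = 2.28e-05, and adjusted p = 0.333 with an estimated correlation. Of 23 cholesterol synthesis genes tested, edgeR called none (2 were lower with p adjusted over the list alone). Of the members 0 were higher and 7 lower at unadjusted p under 0.05, and DESeq2 called 0 and 2. Cholesterol synthesis had camera adjusted p = 0.000207, and adjusted p = 0.0705 with an estimated correlation. Of 27 interferon response genes tested, edgeR called none (none with p adjusted over the list alone). Of the members 6 were higher and 0 lower at unadjusted p under 0.05, and DESeq2 called 4 and 0. The interferon response had camera adjusted p = 0.000478, and adjusted p = 0.539 with an estimated correlation. Of 23 monocyte, macrophage and dendritic cell genes tested, edgeR called none (none with p adjusted over the list alone). Of the members 6 were higher and 0 lower at unadjusted p under 0.05, and DESeq2 called 1 and 0. Monocyte, macrophage and dendritic cell genes had camera adjusted p = 0.0471, and adjusted p = 0.539 with an estimated correlation. Hspa5 had 1.497 (SE 0.29, adjusted p = 0.0609) and Ddit3 1.63 (SE 0.44, adjusted p = 0.121), and Dnajb9 had -0.33, Edem1 had -0.58 and Sec61b had -0.0036 (adjusted p 0.218 to 0.9999). The other 18 lists did not pass, with camera's adjusted p from 0.0634 to 0.963 and from 0.301 to 0.959 with an estimated correlation; 0.0634 was the value for XBP1 targets and for ER chaperones.

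Single libraries and settings moved several of these values for the difference between stages. The list of receptors had adjusted p = 0.131 without GATA2-GMP WT 3 and 0.0651 without GATA2-GMP KO 3 (0.00731 to 0.131 over all fits at the fixed correlation). The monocyte list had adjusted p = 0.0508 without GMP WT 2, 0.106 without GMP KO 1, 0.0506 without GMP KO 3, 0.0585 without GATA2-GMP WT 1, 0.160 without GATA2-GMP WT 3, 0.0723 without GATA2-GMP KO 1 and 0.222 without GATA2-GMP KO 3 (0.00198 to 0.222). With a mean of at least 5 CPM both missed the threshold (adjusted p = 0.0644 each) and lineage transcription factors passed (0.0230), and with the replicate block later granules and stem cell genes passed (0.0320 and 0.0472). XBP1 targets passed with 0.00795 without GMP WT 3, 0.0445 without GMP KO 3, 0.0287 without GATA2-GMP WT 2, 0.0452 without GATA2-GMP WT 3 and 0.04998 without GATA2-GMP KO 2. ER chaperones passed with 0.0249 without GMP WT 3, 0.0298 without GMP KO 3, 0.0273 without GATA2-GMP WT 2 and 0.0452 without GATA2-GMP WT 3, and lineage transcription factors with 0.0397 without GMP WT 1, 0.0249 without GMP WT 3 and 0.0392 without GMP KO 2. Translocation passed with 0.0452 without GATA2-GMP WT 3, primary granules with 0.0452 without GATA2-GMP WT 3, later granules with 0.0156 without GMP WT 1, stem cell genes with 0.0427 without GATA2-GMP WT 1 and immediate early genes with 0.00157 without GMP WT 2. Eosinophil granule members called were none without each GMP library or without GATA2-GMP KO 1, 1 without GATA2-GMP KO 3 and 5 without GATA2-GMP WT 3. Without GATA2-GMP WT 3 and WT 2, members called were 7 and 2 in the PERK arm, 4 and 1 among receptors and 4 and 1 in cholesterol synthesis, and without WT 3 they were 4 in the interferon response and 2 in the monocyte list; without KO 3 the PERK arm had 1. Among single genes, Hspa5 without GATA2-GMP KO 3 (adjusted p = 0.0491), Ddit3, Epx and Hspa5 without GATA2-GMP WT 2 (adjusted p 0.0233 to 0.0474) and Epx, Hspa5 and Prg2 without GATA2-GMP WT 3 (adjusted p 0.00897 to 0.0243) passed.

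Wild-type GATA2-GMP were last compared with wild-type GMP, a contrast in which transduction, re-sorting, culture and library kit change together with the stage and cannot be told apart. Eosinophil transcripts were far higher in GATA2-GMP: Prg2 went from 102 ± 73.5 to 137451 ± 29784 CPM (mean ± SD, n = 3 each), a log2 fold change of 10.40 (SE 0.87, adjusted p = 2.98e-05), with Epx at 9.52 (SE 0.81, adjusted p = 3.21e-05) and Il5ra at 5.98 (SE 0.48, adjusted p = 2.54e-05). Ccr3 had 3 counts in the GMP WT libraries together and 1298 in GATA2-GMP WT, a ratio of 647-fold (95% interval 221 to 3142). Gata1 rose, at 6.62 (SE 0.41, adjusted p = 8.58e-06). Gata2 reads, which may include the vector's, rose, at 3.35 (SE 0.30, adjusted p = 4.25e-05). Cebpe, a factor of terminal granulocyte maturation, rose, at 2.06. Cebpa fell (-4.57), as did Irf8, a factor of monocytes and dendritic cells (-10.48) and the progenitor antigen Cd34 (-4.85). Mpo had -3.00 (SE 0.26, adjusted p = 3.13e-05). Xbp1 rose, at 1.03 (SE 0.25, adjusted p = 0.00602), as did Ddit3 at 3.28, Edem1 at 0.72 (SE 0.18, adjusted p = 0.00845) and Atf4 at 0.68 (SE 0.20, adjusted p = 0.0158), and Ern1 fell, at -5.27. Hspa5 had 0.0030 (SE 0.23, adjusted p = 0.991), Dnajb9 -0.48 (SE 0.30, adjusted p = 0.184) and Sec61b 0.97 (SE 0.42, adjusted p = 0.0676), none past the threshold. Of 12251 genes tested, 4176 rose and 4462 fell, and 77.2% of all genes tested had no overlap between the groups, where chance gives 10%. With a library left out, calls were lost for Edem1 without GMP WT 1 (adjusted p = 0.0518), Atf4 without GMP WT 2 (adjusted p = 0.0824) and Atf4 without GMP WT 3 (adjusted p = 0.0634), and Sec61b without GATA2-GMP WT 3 (adjusted p = 6.40e-05) passed.

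The largest changes by the fixed rule were in genes with few or no reads at 1 stage. Against a floor of 3 counts over the group, Akr1c18 was at least 20245-fold, Car4 at least 5727-fold and Mmp12 at least 2682-fold higher in GATA2-GMP WT, and the Hedgehog receptor component Smo at least 615-fold, Tie1 at least 419-fold, Camk2a at least 314-fold and Cds1 at least 281-fold lower. With 1 count in GMP WT, the endothelial lipase Lipg was higher 62643-fold (95% interval 11243 to 2474327) and Serpinb2 50010.0-fold (95% interval 8975 to 1975362); with 2 and 3 counts in GATA2-GMP WT, the coagulation factor F13a1 was lower 12644-fold (95% interval 3500.0 to 104411) and the heat shock gene Hspa1b 6466-fold (95% interval 2212 to 31358). On mm9, Prg2 lies on chromosome 2 from 84820618 to 84823789 (plus strand) and Epx on chromosome 11 from 87677502 to 87689038 (minus strand).

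By list, more genes of granules and effector cells rose than fell between the stages, and these counts were the same with p adjusted over the list alone. Of 6 eosinophil granule genes 6 rose, and of 17 eosinophil receptors and enzymes 15 rose and 2 fell, with the adenosine receptor Adora3 at 8.39, the receptor subunit Csf2rb2 at 6.74 and the interleukin 33 receptor Il1rl1 at 6.54. Eosinophil granule proteins had camera adjusted p = 0.00125, and adjusted p = 0.517 with an estimated correlation. Eosinophil receptors and enzymes had camera adjusted p = 2.19e-05, and adjusted p = 0.180 with an estimated correlation. Of 23 later neutrophil granule genes 21 rose and 2 fell, with Lcn2 at 7.58 and Anxa1 at 6.12. Later granules had camera adjusted p = 4.94e-07, and adjusted p = 0.267 with an estimated correlation. Of 18 mast cell and basophil genes 16 rose and 1 fell, with the steroid synthesis enzyme Cyp11a1 at 11.12. Mast cell and basophil genes had camera adjusted p = 3.78e-06, and adjusted p = 0.478 with an estimated correlation. Of 23 cholesterol synthesis genes 21 rose and 2 fell, with Fdft1 at 4.38 and Fdps at 4.16. Cholesterol synthesis had camera adjusted p = 3.78e-06, and adjusted p = 0.180 with an estimated correlation. Of 27 p53 targets 19 rose and 5 fell, with the cell cycle inhibitor Cdkn1a at 3.64 and the death receptor Fas at 6.52. The p53 targets had camera adjusted p = 0.00439, and adjusted p = 0.180 with an estimated correlation. Of 34 genes of translocation and N-glycosylation 24 rose and 4 fell, with Sec11a at 2.60 and Dad1 at 3.07. Translocation and N-glycosylation had camera adjusted p = 0.00237, and adjusted p = 0.553 with an estimated correlation. Of 19 immediate early genes 1 rose and 14 fell, with Jun at -10.45 and Junb at -5.24. Immediate early genes had camera adjusted p = 0.00485, and adjusted p = 0.586 with an estimated correlation. Camera's adjusted p for these 8 lists stayed at or under 0.0190 over all fits at the fixed correlation, and 0 passed with an estimated correlation.

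The other 16 lists did not pass in the stage comparison, with camera's adjusted p from 0.0617 to 0.946 and from 0.517 to 0.972 with an estimated correlation. With a library left out, the cell cycle passed without GATA2-GMP WT 2 (adjusted p = 0.0304), with 0.0304 to 0.0915 over all fits at the fixed correlation, and the PERK arm without GATA2-GMP WT 1 (0.0147), with 0.0147 to 0.273.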

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

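The test of other groupings of the libraries, the hypoxia response list and the question of cultures that differed in cell number or oxygen were chosen after the results they concern were seen. The results below stand here because the genotype effect differed between the stages by the interaction test without a replicate block. The difference of log2 fold changes, GATA2-GMP minus GMP, was 2.09 for Pdk1, 1.47 for Slc2a1, 1.37 for Ethe1 and 1.18 for Zcchc11, and -2.13 for Tusc1, -2.24 for Rnf144b, -2.98 for Camkk1, -5.51 for Sncaip, -6.74 for Ear1 and -6.58 for Ear2, the last pair uncertain (adjusted p from 0.00733 for Sncaip to 0.0331 for Tusc1). Each of these but Sncaip missed the threshold without any 1 of the 6 GMP libraries, all 10 with the replicate block or without GATA2-GMP KO 1, Ear2 without GATA2-GMP KO 3 and Slc2a1 without GATA2-GMP WT 1, with adjusted p from 0.0504 to 0.291. The count of 11 genes became 0 in edgeR with the replicate block (1336 at unadjusted p under 0.05) and without GATA2-GMP KO 1 (1687, while DESeq2 called 716 with all libraries), and reached 1179 without GATA2-GMP WT 3. Among 100 regroupings of the libraries within each stage, the real one included, 17 called at least 11 genes, the highest other 1754, so chance is not excluded as a source of the count. The regrouping with 1754 parted the GATA2-GMP libraries as WT 1, WT 2 and KO 3 against WT 3, KO 1 and KO 2, which points to a structure of those samples that is not genotype.

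By list, the median difference was -2.92 (adjusted p = 6.17e-08 and 0.155) for eosinophil granule proteins, -0.55 (adjusted p = 0.0194 and 0.155) for eosinophil receptors and enzymes and -0.46 (adjusted p = 0.000207 and 0.0705) for cholesterol synthesis. It was 0.52 (adjusted p = 2.28e-05 and 0.333) for the PERK arm, 0.28 (adjusted p = 0.0471 and 0.539) for monocytes, macrophages and dendritic cells and 0.78 (adjusted p = 0.000478 and 0.539) for the interferon response. Each bracket gives camera's adjusted p and then the adjusted p with an estimated correlation. The list of receptors missed the threshold without either of 2 libraries, and the monocyte list without any of 7 (adjusted p 0.0506 to 0.222). Under the replicate block these 6 passed camera, as did later granules (0.0320) and stem cell genes (0.0472), and 0 with an estimated correlation.

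The genes with a higher ratio in GATA2-GMP included Pdk1 and Slc2a1, known targets of hypoxia-inducible factors, which rose there with Bnip3 and Ankrd37. Of 37 other known targets tested, 34 were higher in Xbp1-deficient GATA2-GMP, at a median log2 fold change of 0.72. Over all genes 0 passed the threshold, since genes called there were left out, and 18 with p adjusted over the list alone (fry adjusted p = 0.00511 over 3 comparisons, camera 3.65e-13, and 0.0370 with an estimated correlation). The tables argue against a single library as the source, since the median ran from 0.64 without WT 1 to 0.80 without KO 2, and against an effect that is already there in sorted GMP, where the median was 0.052 (fry adjusted p = 0.403, and 0.00330 for the difference between stages). Cultures that differed in cell number or oxygen cannot be told apart from an effect of genotype after GATA2, because the labels give neither. The list's fry p was 0.00341 before adjustment. Mean log2 CPM of the list was 4.69, 4.85 and 4.99 in GATA2-GMP WT and 5.87, 5.48 and 5.81 in GATA2-GMP KO.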

How the results depend on the processing

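The tests of other splits, of length and of exchanged labels for the split named below and all fits with corrected offsets were chosen after the results were seen; a fit with that split as a term was also looked at then and is not reported, because its groups came from the outcome. Where no reason is given for a change below, the cause was not tested. Scaling by DESeq2's size factors moved the median log2 fold change of all genes by less than 0.1 in each comparison (from -0.027 to 0.068).

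In GMP the count of 381 genes was 378 with DESeq2's size factors, 370 with a mean of at least 5 CPM, 460 with no filter and 489 with DESeq2. It was 964 with the replicate block (380 of the 381 among them), 1000 with the block and length-corrected offsets (380), 875 with the block and GC-corrected offsets (376) and 17 with all 12 libraries in 1 fit, where the larger spread of GATA2-GMP enters; without 1 library it ran from 209 (GMP KO 3) over 237 (GMP WT 3) to 398 (GMP KO 1). The real split of the 6 libraries called 381 genes and the highest of the other splits 4; 10 splits, of which 1 reached the real count, are too few for a share under 0.05.

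In GATA2-GMP the count of 44 genes was 43 with DESeq2's size factors, 42 with a mean of at least 5 CPM and 48 with GC-corrected offsets. It was 504 with DESeq2 and 167 with length-corrected offsets, all 44 among each, 294 with no filter, 3 with the replicate block and 1461 with all 12 libraries in 1 fit, where the smaller spread of GMP enters. Without 1 library it ran from 0 in edgeR (KO 1 or KO 3, with 1000 and 1444 at unadjusted p under 0.05) to 525 (WT 3). With the length correction Xbp1 (adjusted p = 0.0384) and Epx (adjusted p < 0.05) passed in GATA2-GMP (0.00185 to 0.456 and 1.02e-05 to 0.457 over all alternatives), and Hspa5 and Epx in the difference (0.0257 and 0.0336, with 2.02e-05 to 0.291 and 2.62e-06 to 0.291).

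The count of 11 for the difference was 17 with DESeq2's size factors (4 higher and 13 lower), 716 with DESeq2, 40 with no filter, 18 with a mean of at least 5 CPM and 81 with length-corrected offsets (28 and 53), the same 11 being among the 17, 716, 40 and 81. It was 0 in edgeR with the replicate block (1336 at unadjusted p under 0.05), and without 1 library it ran from 0 (GATA2-GMP KO 1, 1687 at unadjusted p under 0.05) to 1179 (GATA2-GMP WT 3). The 8638 genes of the stage comparison were 7030 to 9287 under the settings other than leaving out a library, and 7621 (without GMP WT 2) to 9826 (without GATA2-GMP WT 3) under that; 10 splits, of which 1 reached the real count and the other splits called 0 in edgeR at most, are too few for a share under 0.05.

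Of the lists past camera, 16 in GMP, 11 in GATA2-GMP, 6 for the difference and 8 for the stage, 0 passed in each with an estimated correlation, where 7, 7, 3 and 4 had an unadjusted p under 0.05. Fry passed 7, 11, 4 and 20, and 3, 0, 3 and 16 with the replicate block (lowest adjusted p = 0.0747 in GATA2-GMP). In GMP the decay substrates, PERK arm and later granules passed fry with the block (adjusted p = 0.0348 each), and XBP1 targets, ER chaperones, translocation and vesicle transport (0.0541 each) and degradation and sensors (0.0642 each) lost the call. Without 1 library camera passed 13 to 17, 11 to 13, 4 to 9 and 8 to 9. With a mean of at least 5 CPM the monocyte list (camera adjusted p = 0.0533) and the erythroid list (0.135) missed the threshold in GMP, within 5.56e-05 to 0.331 and 0.000564 to 0.148 over all fits at the fixed correlation (adjusted p = 0.541 each with an estimated correlation). The overlap of 20 calls was 107 with DESeq2 and 55 at an adjusted p under 0.1 (6 rises and 49 falls).

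Over all alternatives no named gene reversed. Among values of named genes, 5630 (uncalled genes included) kept their side of the threshold, 428 gained a call, 309 lost one and 41 changed sign with no call in either. Of 26 named GATA2-GMP calls all were lost without KO 1 or KO 3, and of 10 in the difference 9 without any 1 GMP library. DESeq2 lost 0 of either. Member counts of lists were within 1.5 times in 981 cases and outside in 267.

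One other split of the GATA2-GMP libraries, WT 1, WT 2 and KO 3 against WT 3, KO 1 and KO 2, called 1453 genes against 44 for genotype (2 of 10 splits reached 44, which are too few for a share under 0.05), and this points to a structure of the samples. Log ratios to the mean library followed transcript length across genes, which are not independent, with Spearman's rho of -0.195, -0.342 and 0.431 in WT 1, 2 and 3 and 0.274, 0.308 and -0.352 in KO, and from -0.154 to 0.170 in GMP. With length-corrected offsets that split called 375 genes and genotype 167, so length bias may account for much of that split but not all. With GC-corrected offsets it called 1422, which argues against GC content; no biological explanation was tested. An exchange of the labels of WT 3 and KO 3 would give this split too, but the 293 genes that fell in GMP had a median log2 CPM difference of -0.69 from WT 3 to KO 3, with 72.0% lower in KO 3, which argues against it.

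Libraries spread more widely in GATA2-GMP, where 13.4% of simulated 2-fold changes were recovered, against 88.1% in GMP.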

Other observations

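Sva was singled out, and the tests of this part were chosen, after its counts were seen and before the results of these tests were.

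Sva, the seminal vesicle antigen, on chromosome 6 from 41988393 to 41992850 (plus strand) of mm9, had 0 counts in all 6 WT libraries and 49, 71 and 17 counts in GMP KO 1, 2 and 3 and 42, 47 and 43 in GATA2-GMP KO, at least 37.1-fold and 44.0-fold higher against a floor of 3 counts over the group. Reads from a near-identical gene are argued against among annotated coding transcripts, of which the closest, Sval1, matched at 69.8% over 172 bases. A chromosome segment around Sva that differs between the genotypes may be a source: of 33 tested genes within 5 megabases, 7 had an unadjusted p under 0.05 in GMP (21.2% against 14.4% of other genes, Fisher's exact p = 0.316, two-sided). This test cannot decide it, and so such a segment cannot be told apart from an effect of Xbp1, which lies on chromosome 11. Of the 33 neighbours 1 was called, Creb3l2, which also had the largest fall of the GMP comparison by the naming rule.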
